A study of Mus musculus with 6 samples.

How the data were processed

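Messenger RNA of 6 single blastocysts was measured, 3 per group. Per the labels' protocols, whole embryos were lysed, cDNA was made with the SMART-Seq v4 ultra-low-input kit, which does not mark strand, and libraries were sequenced on Illumina instruments. The labels do not say which embryos share parents or an injection day, or whether the small RNAs of a group came from separate males. The p-values of single genes and of embryo means thus measure the spread between these embryos. Those of camera at its preset correlation set the member genes of a list against other genes, and do not measure that spread. The submitters' processing notes name HISAT2, Cufflinks 2.2.1 and the mm10 build without saying what each did. The counting program and annotation are not given in the sources used here.

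The deposited table holds 1 signal value per gene and library, per its values a read count divided by 1 size factor per library, and per the file headers the mean over libraries, a log2 fold change with its standard error, a test statistic (score), a p-value and an adjusted p-value. These header names are those of a DESeq2 results table. The low values in each library were whole multiples of a step, and dividing by it gave whole reads for 100% of values in each library, within a tolerance of 0.01. For Dep 2 the step is 0.993, so near 1 that its reading as a size factor rests on its values matching the other columns in kind. DESeq2 run on the recovered reads gave log2 folds within 4.26e-08 of the deposited ones. The lowest mean in the table is 14.2 normalized counts, so genes with fewer reads were left out before deposit, and depth here means reads in listed genes, from 16543356 to 21548220 per library. No molecular identifiers are described, so reads are not independent molecules. Reads of overlapping or antisense genes cannot be told apart without strand.

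Gene names, positions and exon lengths came from GENCODE M21 on GRCm38, the assembly that mm10 names, by Ensembl identifier. Of the 12149 identifiers, 11829 matched and 320 did not and kept their identifier. FPKM, used for numbers of detected genes, was computed from recovered reads and these lengths.

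The design written before the data were examined expected FPKM or counts. As the values are normalized counts, the test planned for FPKM was used on log2(normalized count + 1): limma 3.58.1 with a mean-variance trend, Dep against Ctl, Benjamini-Hochberg adjustment and a threshold of 0.05. Log2 folds are on this scale and understate changes of low genes. edgeR 4.0.16 (quasi-likelihood) and DESeq2 1.42.0 on recovered reads were alternatives added after the data were seen. R was 4.3.3 and Python 3.11.15. Of 38 gene lists fixed before the data were examined, 33 had at least 5 measured members and were tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry. The estimated correlation and fry were run in the main setting alone, so list calls in other settings use the preset correlation. The lists of blood, fibroblast, neural signalling and sperm genes and of Xist had 2, 1, 4, 3 and 1 measured members and were not tested. List scores and library measures were compared with two-sided exact permutation tests. The fit and list tests were tested on simulated data with 200 changed genes.

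The naming rule, fixed beforehand, took genes past the threshold and, as fewer than 20 passed, 12 higher and 12 lower genes of smallest unadjusted p whose groups do not overlap and whose higher group reaches 20 CPM, given as values. It passed over 1 gene model without a name. It also took up to 4 members of smallest p from each list discussed, and a fixed set of lineage, sex, small RNA, methylation and receptor genes. Some genes that the rule took are not reported here. mt-Co1 falls outside the rule and was chosen after its values were seen. The libraries are not duplicates of each other by a chi-square test of their reads.

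Both groups are numbered 1 to 3. Deviations from the group means correlated between same-numbered embryos with r = 0.133, 0.151 and 0.129 across genes, each over 0.1, and each library correlated best with its own number in the other group. By the rule set beforehand the numbers were taken to pair the embryos, a pairing that comes from this check and not from the labels. Deviations within a group sum to 0, so these correlations are tied together and cannot all be low. How often the numbers would match best by chance was not assessed. A fit with the number as a block was an alternative. Other alternatives were the pseudocount, 2 rescalings, library weights, each embryo left out, a Y-linked covariate, X and Y genes left out, no trend, FPKM values, a minimum mean of 100 and the removal of Ctl 2, Dep 2 and Dep 3.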

Results

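RNA of single mouse blastocysts (embryonic day 3.5, C57BL/6) was sequenced after zygotes had been injected with small RNAs from sperm at 2 ng/µl. The small RNAs came from normal males in the control group (Ctl, 3 embryos) and from males made depressive by stress in the other group (Dep, 3 embryos). The blastocyst consists of trophectoderm, which forms the placenta, and an inner cell mass that separates into epiblast and primitive endoderm. Embryos were collected about 96 h after injection. The table gives normalized counts of 12149 genes in each of the 6 libraries.

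The whole reads behind these values summed to 16543356 in Ctl 1, 21548220 in Ctl 2, 19864426 in Ctl 3, 17213406 in Dep 1, 18263929 in Dep 2 and 19439008 in Dep 3. Genes at 1 FPKM or more numbered 10008 ± 200.2 in Ctl and 9875 ± 641 in Dep (SD, n = 3 each; two-sided exact permutation test, p = 0.8). Dep 1 stood apart, with 691 listed genes at 0 reads, against 5 to 106 in the other libraries. Mitochondrially encoded transcripts took 5.97% ± 1.83 of the reads in Ctl and 3.59% ± 0.486 in Dep (SD, n = 3 each; exact permutation p = 0.2). The smallest two-sided p that 3 against 3 embryos can give is 0.1.

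The comparison of Dep with Ctl asks whether the small RNA content of sperm from stressed fathers alters gene expression in the early embryo. Genes of sterol synthesis rose as a group in Dep: 19 of 23 measured members had a higher mean log2 level, with a median log2 fold of 0.51 (limma camera, adjusted p = 2.58e-09; adjusted p = 0.835 with an estimated correlation). Fdps, the synthase of farnesyl diphosphate, had 1755 ± 659.9 normalized counts in Ctl and 5759.7 ± 3010.0 in Dep (SD, n = 3 each). Mvd, which makes isopentenyl diphosphate, had 360.2 ± 73.3 and 933 ± 341, and Insig1, an endoplasmic reticulum protein that restrains activation of the sterol-responsive SREBP factors, 505 ± 122 and 1228 ± 539. Fdft1, the squalene synthase, had 1239 ± 549 and 2711 ± 951. Adjusted over the list alone, Fdps passed the threshold (adjusted p = 0.0369), and over all genes tested 0 members did. The mean log2 level of the list was 9.05 ± 0.23 in Ctl and 9.62 ± 0.55 in Dep (SD, n = 3 each), and an exact permutation test of these embryo means gave p = 0.3. Dep 2 and Dep 3, at 9.94 and 9.93, lay above the 3 Ctl embryos, and Dep 1, at 8.98, lay among them. The median was 0.78 without Dep 1, and -0.04 with adjusted p = 0.965 without Ctl 2, Dep 2 and Dep 3.

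**Figure D1:**
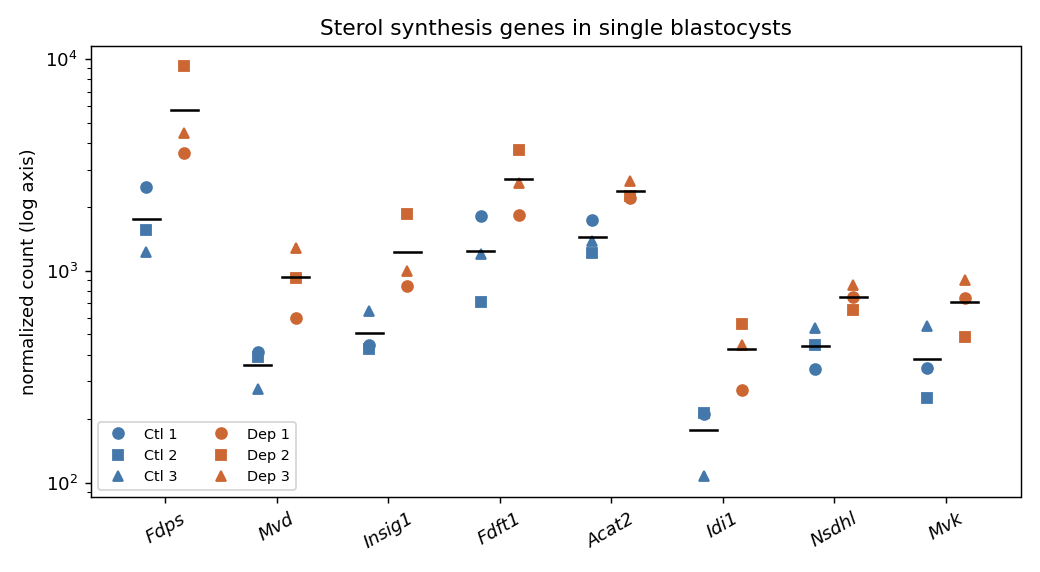
Normalized counts (log axis) of the 8 sterol synthesis genes of smallest unadjusted p, for each Ctl and Dep blastocyst, with black bars at the group means of 3 embryos. For Fdps the Dep embryos lie between 3598 and 9198 and the Ctl embryos between 1223 and 2494.

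Acly and Scd1, genes of lipid synthesis outside that list, were also among the 12 with higher values in Dep that the naming rule took. Acly, which makes cytosolic acetyl-CoA from citrate, had 1765 ± 185 normalized counts in Ctl and 4479 ± 1595 in Dep, a log2 fold of 1.27 ± 0.32 (SE). Scd1, a desaturase of fatty acyl-CoA, had 2554 ± 1104 and 5336 ± 1433. The endonuclease gene Mus81 had 127 ± 35.8 and 403 ± 144, and Bcs1l, an assembly factor of respiratory complex III, 161 ± 41.3 and 535 ± 294. The others were Bloc1s3, BC004004, BC030867, C1qtnf12 and Dph7, with log2 folds from 1.02 to 1.47. Each of these values is a mean ± SD over 3 embryos per group. None of these genes passed the test over all genes (limma, adjusted p = 0.9997 for each). A further 19 lipid genes, picked before their values were seen, had a median log2 fold of 0.0454, with 12 higher and the rest lower.

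Ly6a, which encodes a surface protein anchored in the membrane by a lipid, had the smallest unadjusted p of the genes with lower values in Dep. It had 12467 ± 7698 normalized counts in Ctl and 3565 ± 483 in Dep (SD, n = 3 each), a log2 fold of -1.65 ± 0.38 (SE), and 21349 in Ctl 1 alone. Ceacam10, of the carcinoembryonic antigen family, had 4919.6 ± 1529 and 2029 ± 253. Piwil2 and Mael, both known from the piRNA pathway of the germ line, had 513 ± 55.7 against 191 ± 69.3 and 667 ± 264 against 241 ± 89.9. Cd81, an imprinted tetraspanin gene, had 1374 ± 162 and 593 ± 299. Sept6, Slc38a11, Togaram1, Vps50, Zfp948 and Naa11 were also among the 12 with lower values, with log2 folds from -2.35 to -0.86. In GRCm38, Ly6a (ENSMUSG00000075602) spans 74994877 to 74998031 on chromosome 15, Ceacam10 (ENSMUSG00000054169) 24777206 to 24784657 on chromosome 7 and Fdps (ENSMUSG00000059743) 89093588 to 89101959 on chromosome 3, each annotated as protein-coding. Ly6a and Ceacam10 belong to families of similar genes, so the division of reads between relatives is uncertain.

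Over all 12149 genes, 0 passed an adjusted p of 0.05 by limma, and 225 had an unadjusted p under 0.05 (101 higher and 124 lower in Dep), against 607 expected by chance. That count was 122, 228 and 137 without Ctl 1, 2 and 3, and 474, 349 and 576 without Dep 1, 2 and 3. It was 143 with a Y-linked covariate, 399 with library weights and 420 with the replicate number as a block. edgeR on the recovered reads called 0 genes and had 211 at the unadjusted threshold. DESeq2 on the same reads called 1, Ly6a (adjusted p = 0.0345), as does the authors' deposited table. On data simulated with the spread of these embryos and 200 changed genes, DESeq2 made 40 false calls, and limma and edgeR 10 each. With that many true changes the adjusted threshold admits larger unadjusted p-values than in the real data. These counts therefore do not judge the Ly6a call. The groups did not overlap in 838 genes, or 6.90%, where chance gives 10%. In the same simulation limma called 4.48% of genes changed 2-fold, 53.7% of those changed 4-fold and 90.9% of those changed 8-fold. Without Ctl 2, Dep 2 and Dep 3, which besides Y-linked reads had Xist at 36.7% or more of the level of Ctl 1, 580 genes passed, 509 of them lower, but Dep is then Dep 1 alone, assumed to vary like the Ctl embryos.

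The 13 protein-coding genes of the mitochondrial genome fell as a group in Dep, with all 13 lower and a median log2 fold of -0.68 (camera, adjusted p = 3.01e-06; adjusted p = 0.835 with an estimated correlation). mt-Nd2 had 73978 ± 32569 normalized counts in Ctl and 36653 ± 16256 in Dep, and mt-Co1, a subunit of cytochrome oxidase, 253446 ± 58760.2 and 161394 ± 16190.2 (SD, n = 3 each). Adjusted over the list alone, the smallest limma p was 0.265. Ctl 2, with 36724 for mt-Nd2, lay in the range of the Dep embryos, and without it the median was -1.12. The mean log2 level of the list was 13.65 ± 0.74 in Ctl and 12.96 ± 0.40 in Dep (SD, n = 3 each; exact permutation p = 0.3). Nuclear genes for mitochondrial ribosomal proteins rose as a group, 64 of 73 being higher (median 0.19, adjusted p = 5.94e-06; adjusted p = 0.835 with an estimated correlation). Cytosolic ribosomal proteins (68 of 85 higher, median 0.14, adjusted p = 0.00515) and proteasome subunits (32 of 36 higher, median 0.15, adjusted p = 0.0154) also passed, each with adjusted p = 0.835 with an estimated correlation. Examples are Mrpl38, at 1129 ± 203 and 1825 ± 729.6, Rpl15, at 9553 ± 2386 and 13115 ± 4780.2, and Psmc5, at 5906 ± 1913 and 10287 ± 6729. Adjusted over the list alone, the smallest limma p was 0.956 for mitochondrial and 0.992 for cytosolic ribosomal proteins. The 2 ribosomal groups leaned on Dep 1. Without it the adjusted p was 0.973 for mitochondrial ribosomal proteins (median 0.03), and the cytosolic ones turned to a median of -0.15 (adjusted p = 0.00300). The proteasome lost its call without Dep 1 too (0.309, median 0.08). The ribosomal list also lost its call without Ctl 2 (adjusted p = 0.825, median -0.02) or Ctl 3 (0.108, median 0.08), and the proteasome without Ctl 3 (0.984, median -0.01) or Dep 2 (0.599, median -0.05). Quantile normalization ended both calls (0.137, median 0.08, and 0.0842, median 0.10), and library weights that of the ribosomal list (0.624, median 0.01). Without Ctl 1 or Dep 3 the medians were larger, at 0.30 and 0.43 for mitochondrial ribosomal proteins, 0.31 and 0.33 for cytosolic ones and 0.30 and 0.43 for the proteasome, which had 0.24 without Ctl 2. The proteasome median was 0.31 with a Y-linked covariate and 0.27 with library weights, and the cytosolic ribosomal one 0.22 with the covariate. Without Ctl 2, Dep 2 and Dep 3 the medians were 0.53 for mitochondrial ribosomal proteins, 0.57 for cytosolic ones and 0.34 for the proteasome.

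Imprinted genes fell as a group, 23 of 32 being lower (median log2 fold -0.39, camera adjusted p = 0.00507; adjusted p = 0.835 with an estimated correlation). Besides Cd81, Peg3, a paternally expressed zinc finger gene, had 1031 ± 486 normalized counts in Ctl and 410.4 ± 269 in Dep, and Grb10, an adaptor of growth factor receptors, 487 ± 50.1 and 284 ± 211 (SD, n = 3 each). Genes of Wnt, FGF and TGF-beta signalling fell (23 of 26 lower, median -0.36, adjusted p = 0.00515), as did antioxidant genes (20 of 25 lower, median -0.34, adjusted p = 0.00674), both with adjusted p = 0.835 with an estimated correlation. Ctnnb1, the beta-catenin gene, had 6448 ± 671 and 4769 ± 212, Fgf4, the growth factor of the epiblast, 231 ± 192 and 55.3 ± 50.9, and the glutathione transferase gene Gsto1 70286 ± 2762 and 43904 ± 9914. Genes of the integrated stress and endoplasmic reticulum responses rose as a group, 19 of 27 being higher (median 0.30, adjusted p = 0.0154; adjusted p = 0.835 with an estimated correlation). Its members went both ways: Asns, asparagine synthetase, had 449 ± 383 and 1015 ± 355, and Ppp1r15a, a phosphatase subunit that reverses the translational arrest of this response, 635 ± 169 and 328 ± 66.1. Adjusted over each list alone, the smallest limma p was 0.258 for imprinted, 0.579 for signalling, 0.610 for antioxidant and 0.368 for stress genes. The groups overlapped for Fgf4 and Grb10. Leaving out Dep 1 ended the call for imprinted genes (adjusted p = 0.135, median -0.14) and signalling (0.853, median -0.02), and leaving out Dep 3 that for antioxidant genes (0.416, median -0.12), whose median was -0.20 without Ctl 1 and -0.58 without Dep 2. The stress list lost its call without Ctl 1 (0.107, median 0.23), Ctl 3 (0.277, median 0.07) or Dep 2 (0.599, median 0.04). The imprinted list kept its call at smaller medians with library weights (-0.17), edgeR (-0.20) and FPKM (-0.09), as did signalling (-0.22, -0.18 and -0.23), and the antioxidant median was -0.18 with edgeR. Without Ctl 2, Dep 2 and Dep 3 the antioxidant (0.320, median -0.20) and stress lists (0.306, median 0.16) did not pass, and the signalling median was -1.04.

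**Figure D2:**
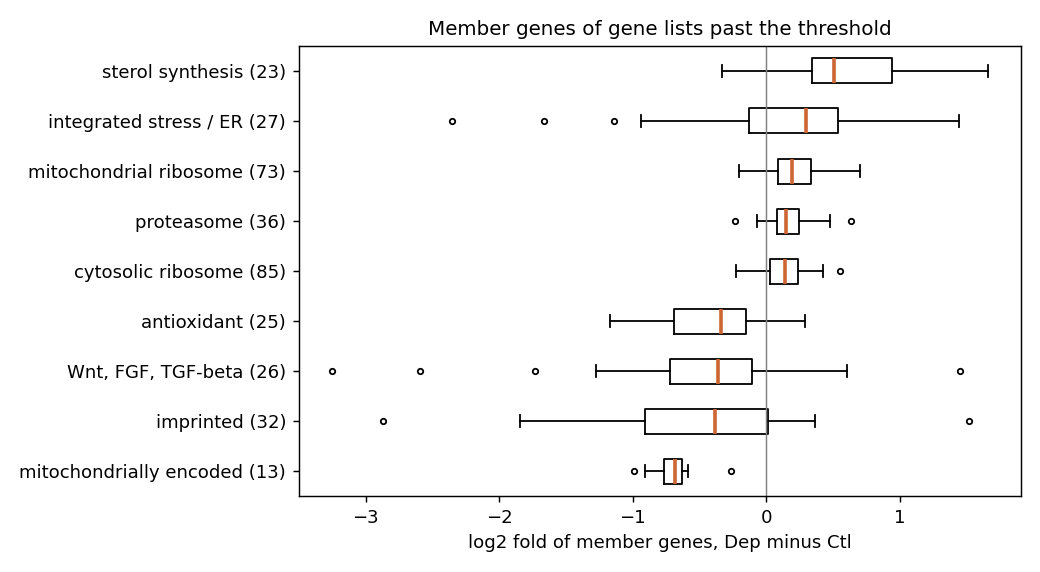
Log2 fold (Dep minus Ctl) of the member genes of 9 lists past the threshold, with the number of members in brackets. Boxes span the quartiles, the orange line is the median, whiskers reach the farthest gene within 1.5 box lengths and circles are genes beyond; medians run from -0.68 for mitochondrially encoded genes to 0.51 for sterol synthesis.

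Differences in markers of the embryo's cell lineages between the groups lay within the spread of the embryos. The epiblast gene Nanog had 2899 ± 261 normalized counts in Ctl and 3886 ± 1733 in Dep (SD, n = 3 each), Pou5f1 3219.9 ± 1154 and 3141 ± 646, and Sox2 296 ± 55.9 and 216 ± 61.5. The trophectoderm gene Cdx2 had 2062 ± 355 and 2735 ± 1022, and Gata3 7676 ± 1076 and 7396 ± 3064. Gata6, of the early inner cell mass and primitive endoderm, had 5676 ± 643 and 4555 ± 1964. Mean log2 levels were 10.31 ± 0.13 and 10.15 ± 0.73 for the epiblast list, 10.86 ± 0.28 and 10.61 ± 0.26 for trophectoderm and 8.13 ± 0.97 and 8.13 ± 2.07 for primitive endoderm, with exact permutation p = 0.9, 0.6 and 1 (SD, n = 3 each). Primitive endoderm varied most within groups: Sox17 had 121, 115 and 0.883 normalized counts in Ctl 1, 2 and 3, and 0, 327 and 582 in Dep 1, 2 and 3. Without Dep 1 the primitive endoderm list was higher in Dep, with a median log2 fold of 0.94 (camera, adjusted p = 7.40e-08), as with library weights (0.66, 0.00977). Both calls use the preset correlation alone. The mean log2 level of the list was 9.34 in Dep 2 and 9.31 in Dep 3, against 8.01, 9.15 and 7.23 in Ctl 1, 2 and 3. The epiblast (adjusted p = 0.950), trophectoderm (0.464) and, over all 6 embryos, primitive endoderm lists (0.865) did not pass, nor did genes of the oocyte (0.865), of zygotic genome activation (0.474) and of cumulus and granulosa cells (0.399). Trophectoderm passed as lower without Dep 1 (median -0.19, 0.0303) and with library weights (-0.22, 0.0377), and zygotic genome activation as lower without Dep 1 (-0.47, 0.0275).

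**Figure D3:**
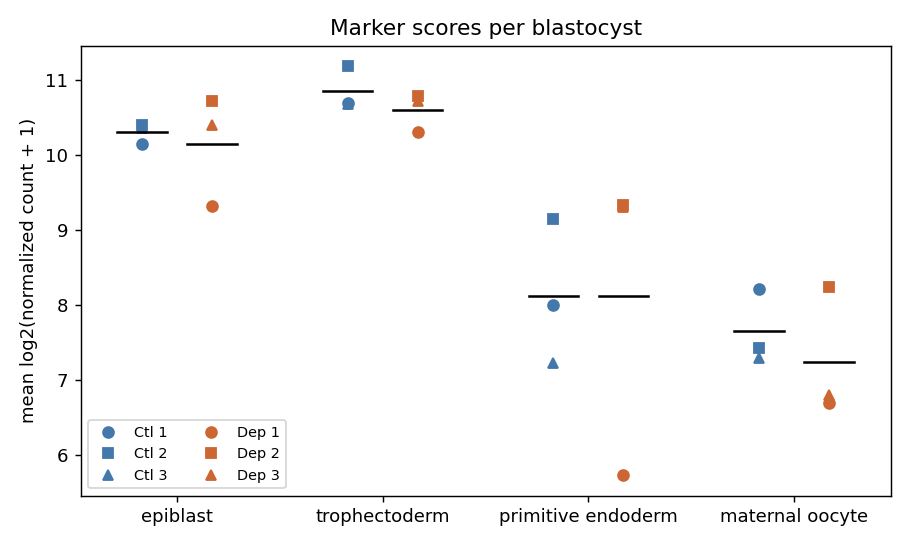
Mean log2(normalized count + 1) of the measured markers of 4 lists in each blastocyst, with black bars at the group means of 3 embryos. Dep 1 has the lowest primitive endoderm value, 5.73, and the other embryos lie between 7.23 and 9.34.

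Genes of small RNA, chromatin and glucocorticoid pathways did not pass the test. The microRNA pathway (10 of 29 members higher, camera adjusted p = 0.592), DNA methylation (8 of 20 higher, 0.223), histone modifiers (18 of 45 higher, 0.528) and glucocorticoid response genes (6 of 16 higher, 0.592) gave no call. Dicer1, which cuts microRNA precursors, had 800.1 ± 147 normalized counts in Ctl and 778 ± 157 in Dep, and Ago2, the microRNA-guided slicer, 2823 ± 737 and 1999.9 ± 864 (SD, n = 3 each). The DNA methyltransferase genes Dnmt3a and Dnmt3b had 1126 ± 379 against 1188 ± 374 and 2605 ± 27.3 against 2855 ± 577. Nr3c1, the glucocorticoid receptor, had 298 ± 78.3 and 266 ± 118. Nuclear genes of oxidative phosphorylation (43 of 63 higher, adjusted p = 0.0935) and Hippo pathway genes (15 of 18 lower, 0.122) did not pass, and did with the replicate number as a block (0.0230 and 0.0485). Oxidative phosphorylation passed in both directions with an embryo left out: as lower without Dep 1 (median -0.25, 8.40e-07), and as higher without Ctl 1 (0.25, 5.70e-06), Dep 2 (0.23, 0.00124) or Dep 3 (0.29, 3.27e-07), as it also did with a Y-linked covariate (0.18, 0.00145). All of these calls use the preset correlation alone. Hippo genes also passed with library weights (0.0181), a Y-linked covariate (0.0242) or without Dep 3 (0.0311). Histone genes (0.104), glycolysis (0.227), heat shock (0.399), neural development (0.399), tight junction (0.464), lysosome and autophagy (0.474), splicing (0.528), p53 target (0.528), interferon (0.528), cell cycle (0.865) and apoptosis genes (0.998) did not pass. Leaving out Dep 3 gave calls for histone genes (0.0114) and for DNA methylation, neural development, lysosome and splicing genes (0.0311 each), leaving out Ctl 1 for histone genes (0.0215) and leaving out Ctl 3 for glycolysis (0.0252). Histone genes also passed with a Y-linked covariate (0.0242) and with FPKM values (0.0411). Without Ctl 2, Dep 2 and Dep 3, histone (0.00844), oxidative phosphorylation (5.03e-13), splicing (0.0101), interferon (0.0220) and p53 target genes (0.0234) passed. Median, mean and test differed in sign for heat shock, lysosome, primitive endoderm, cell cycle and apoptosis genes.

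Sex-linked transcripts differed between embryos within each group. Xist, the RNA that coats the inactive X chromosome of female cells, had 10312 normalized counts in Ctl 1, 5518 in Ctl 2, 874 in Ctl 3, 151 in Dep 1, 3784 in Dep 2 and 5589 in Dep 3. The Y-linked Ddx3y had 1.18, 1159.7 and 2202 in Ctl 1, 2 and 3, and 1424, 266 and 1141 in Dep 1, 2 and 3. The Y-linked list passed the test as higher in Dep (5 of 5 members, adjusted p = 0.0252; adjusted p = 0.835 with an estimated correlation), although the mean of Ddx3y was higher in Ctl (1121 against 944), because Ctl 1 has almost no Y-linked reads. The median log2 fold of the list was -0.98 without Ctl 1 (adjusted p = 0.0568) and 3.91 without Ctl 3, and its call also ended without Dep 1 (0.199) or Dep 3 (0.138), with library weights (0.335, median 0.98) and with edgeR (0.112, median 0.28).

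**Figure D4:**
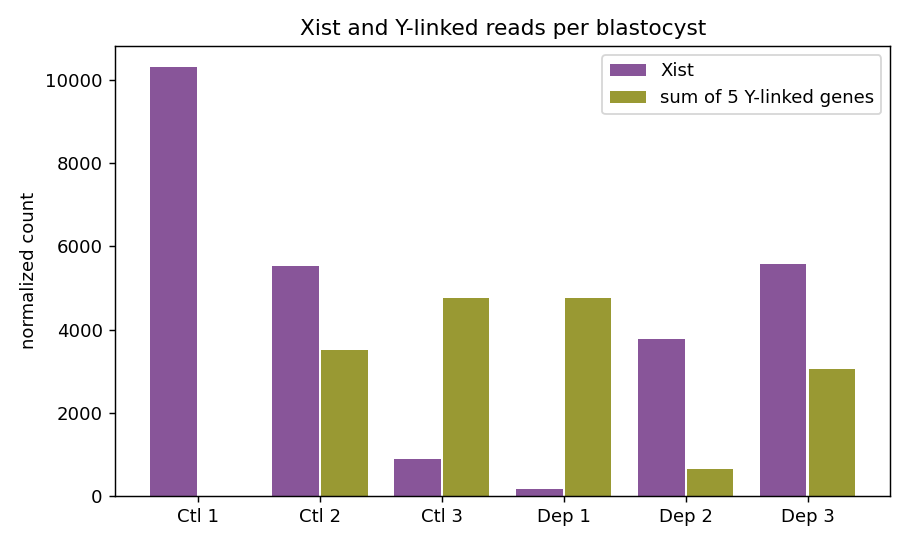
Normalized counts of Xist and of 5 Y-linked genes summed, in each blastocyst. Ctl 1 has Xist with 2.37 Y-linked normalized counts, and the other 5 have Y-linked counts with Xist at 53.5% (Ctl 2), 8.47% (Ctl 3), 1.46% (Dep 1), 36.7% (Dep 2) and 54.2% (Dep 3) of the level of Ctl 1.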

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

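The edgeR and DESeq2 runs, the FPKM values, the minimum mean of 100 and the removal of Ctl 2, Dep 2 and Dep 3 were chosen after seeing the data. The count of 0 genes held in every setting but 2: DESeq2 called 1, and removing Ctl 2, Dep 2 and Dep 3 gave 580, a setting that leaves Dep with 1 embryo. The 10 list calls became 0 with an estimated correlation and 0 with fry, 8 to 15 with each embryo left out, and 8 to 13 elsewhere. The replicate block left 0 genes and gave 12 lists, adding oxidative phosphorylation and the Hippo pathway, and changed no other call. Leaving out 1 embryo moved the median log2 fold from -0.25 to 0.29 for oxidative phosphorylation, from -0.0518 to 0.43 for the proteasome (-0.0116 without Ctl 3), from -0.15 to 0.33 for cytosolic ribosomal proteins, from -0.98 to 3.91 for Y-linked genes and from 0.0321 to 0.43 for mitochondrial ribosomal proteins, whose test turned to lower without Dep 1. Oxidative phosphorylation passed as lower without Dep 1 and as higher without Ctl 1, Dep 2 or Dep 3. Removing Ctl 2, Dep 2 and Dep 3 turned the primitive endoderm test from higher to lower, with the median going from -0.11 to -1.25. The cause of these turns was not tested. Sterol synthesis kept its call with each embryo left out (0.38 to 0.78). The 24 genes taken by size of p kept their sign in every setting. Their groups were chosen not to overlap, so leaving out embryos could not turn a sign, and this is no test of stability. Lineage scores and library measures moved by less than 1 SD of the more variable group. Leaving out 1 of 3 embryos cannot move a group mean that far, so for those settings the bound shows no stability. The primitive endoderm list passed as higher without Dep 1. The planned filters on a mean of 1 or 5 removed no gene and gave no separate value. At this spread 2-fold changes were mostly missed in simulation (4.48% called).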

Other observations

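Tests chosen after the results they bear on were seen are those on splits of the embryos, on Xist and Y-linked reads and on Dep 1. The lipid genes were also added after the data were seen, to follow up the sterol result. The bounds for them and for GC content, length and level were written before those tests. Within the trophectoderm list, the keratin gene Krt19 had 112, 1146 and 38.8 normalized counts in Ctl 1, 2 and 3, and 0, 102 and 32.9 in Dep 1, 2 and 3.

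The sterol synthesis list was higher in Dep (median log2 fold 0.51). A trend of log2 folds on GC content, length and level is argued against as its cause, since removing it left a median of 0.58. Another hypothesis, raised by Acly and Scd1, is that a wider lipid programme moved with it. The 19 further lipid genes, picked before their values were seen, had a median of 0.0454 (percentile 67.9 among matched random lists). That met the bound written against the hypothesis. It is left open only because 12 were higher and the rest lower, with an SD of 0.71, a condition on spread that the written bound did not hold. Of the 10 splits of the embryos, 2 gave the list as small a p, the real -log10 p being 10.1 and the highest other 10.9 (Ctl 1, Dep 2 and Dep 3 against the rest), and 10 splits cannot give a share under 0.05. That other split also parts all same-numbered pairs. Dep minus Ctl of the list score was -0.24, 1.16 and 0.80 in pairs 1, 2 and 3. An effect of the injected small RNAs was not tested apart from this comparison.

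Ctl 2, Dep 2 and Dep 3 had Xist at 53.5%, 36.7% and 54.2% of the level of Ctl 1 together with Y-linked reads. Ctl 3 and Dep 1 also had both, with Xist at 8.47% and 1.46%, and served as the reference; this division was made after the values were seen, without a cutoff set beforehand. Antisense Tsix reads counted as Xist stay open. Xist over Tsix varied 14.6-fold among the 5 libraries with Y-linked reads, which met the bound set against them. But it was 120, 190.5 and 201 in Ctl 2, Dep 2 and Dep 3, and 22.0 and 13.8 in Ctl 3 and Dep 1. Without strand, reads where Xist and Tsix overlap cannot be told apart, so the ratio does not decide. An even exchange of reads among libraries is argued against, since Ctl 1 held 0.0707% of the mean Y-linked level of the others. Xist silencing the single X of a male embryo by 0.3 or more on the log2 scale stays open in Dep 3, and on 1 of the measures in Ctl 2 and Dep 2. X-linked against autosomal genes were measured in 2 ways, relative to Ctl 3 and Dep 1. In Ctl 2 and Dep 2 the lower value was 0.0314 ± 0.0845 (bootstrap SE over genes), which met the bound set against silencing. On that measure, the ratio of medians, Ctl 3 and Dep 1 themselves lay at -0.154 and 0.154. The reference is thus too uneven to decide on an effect of 0.3. In Dep 3 the measures disagree: the median change was -0.0745 ± 0.0418 and the ratio of medians -0.377 ± 0.120 (bootstrap SE). RNA of a female and a male embryo in 1 library stays open as a candidate explanation: at equal depth Ctl 2, Dep 2 and Dep 3 had at most 25 undetected genes, against at least 73 in the others, but X-linked genes were below the reference in Dep 3, where the prediction needed them at or above it. No biological explanation tied to the groups was tested.

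Dep 1 lacked reads for the most genes. Sequencing depth is argued against, since thinned to 16543356 reads it had 695 undetected genes against at most 106 elsewhere. Missing epiblast cells stay open: 13 of 20 epiblast markers were at or over 0.5 of the mean of the others (Nanog 2463, Pou5f1 2767 and Dppa5a 88341 normalized counts), short of the bound of 2 in 3 set against it, while Tdgf1, Fn1, Spp1, Fgf4, Esrrb, Gdf3 and Klf2 were lower and the list score was 9.33 against 10.16 to 10.72. Of the 11 markers with a mean of at least 1000, the version of this test run first, 8 were at or over it. Few or no primitive endoderm cells is a candidate explanation for part of this: 6 of 21 markers were at 0 (Sox17, Amn, Foxq1, Gata4, Sox7 and Creb3l2), 7.04 times the share of genes matched on level. Sox17 and Gata4 had been seen at 0 before that test, the matched genes may vary less between embryos than lineage markers, and a poorer library was not tested. The share was not tested for trophectoderm, whose markers Krt19, Pecam1, Aqp8 and Hand1 were also at 0 in Dep 1 (Hand1 in Ctl 1 too). Of 624 genes at 0 only in Dep 1, 132 had a mean of at least 100 elsewhere. Ctl 3 had Gata4 at 0 and Sox17 at 0.883 with only 70 listed genes at 0.

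The 225 genes at an unadjusted p under 0.05 compare with up to 1015 in the other 9 splits, 8 of the 10 splits giving as many, and the 10 lists with up to 14, 4 of the 10 splits giving as many; a share under 0.05 cannot be had from 10 splits. For the mitochondrially encoded list 3 of the 10 splits gave as small a p, the real -log10 p being 6.74 and the highest other 12.6. The 2 others keep a same-numbered pair together. The 3 other splits that part all pairs gave 0.17 to 3.64, and the list was lower in Dep in 3 of 3 pairs. Neither 4 such splits nor 3 pairs can give a share under 0.05. The exact permutation test of its embryo means (p = 0.3) does not use the pairs. The splits that keep a same-numbered pair together gave 334 to 1015 genes, and the 3 others that part all pairs gave 167 to 249 genes and 4 to 9 lists. The numbers were taken as pairs from correlations in the same values, so these counts are no separate evidence for the pairing.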
